A study of Mus musculus with 42 samples.

How the data were processed

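The deposited values were FPKM, computed by the authors before deposit and listed separately for the maternal and the paternal allele. The submitters' processing notes name Trim Galore 0.6.4 for trimming, HISAT2 2.2.0 for alignment, StringTie 2.1.1 for quantification and the mouse assembly mm9. The method that assigned reads to alleles was not given in the sources used here. The stage table held 24083 genes, the table of control and Xp XRRa KO morulae 23986 and the table of EedmNull embryos held 1052 X-linked genes. In the stage table and the morula table, replicates were pooled by the authors into 1 column per allele and group; the epiblast and yolk sac columns stood for 1 sample each. The columns are printed as the authors' values. The tables were normalized separately, and levels were compared within a table unless a sentence says otherwise. 5 summary lines were left out. The tables gave no counts, so depth was unknown and no interval for depth was computed.

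Gene totals were the sum of both alleles, and the paternal share was the paternal FPKM over that sum for genes with a total of at least 1 FPKM. Xist shares of EedmNull embryos were used without that minimum. A gene listed at 0 for both alleles can be silent or lack reads that tell the alleles apart, so no ratio was printed against a 0. Medians over genes have 95% order-statistic intervals, which describe spread over genes and not over embryos. The reference annotation (GRCm38.p6) differs from the mm9 of the files; it was used only for chromosome, names and order of neighbours, with no coordinates printed, and 23959 of 24083 genes were matched to it. Of the 1052 genes of the X list, 1044 were also on the X there.

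For pooled columns a fixed rule of size was used in place of a test: at least 5 FPKM in 1 column and a ratio of at least 2 on FPKM plus 1. Log2 ratios between columns and folds of medians were also on FPKM plus 1. They can therefore be smaller than ratios of the printed FPKM. Medians of fixed gene lists were set beside 10000 random lists matched for expression. The random genes were drawn independently, so these percentiles hold no spread between embryos. In pooled columns they are not a test of a group difference. For EedmNull embryos, log2 ratios of paternal to maternal FPKM plus 1 and slopes on the embryo median were fitted with limma, and p-values were adjusted by the Benjamini-Hochberg method. The embryo mean was tested by 100000 sign flips and correlations by 100000 permutations with seed 7. Genes named in the text were up to 10 with the largest ratio in each direction, members of fixed lists and up to 4 examples per list, and genes with the highest and lowest shares.

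Procedures were tested on simulated data. In 300 simulated genes with the embryo-wide shift of these samples, limma found 0% of added ratios of 1 log2, and without that shift 88%; the slope fit found 100 of 100 genes with a slope of 0.4 and 4 of 200 others. The random-list percentile, run on 7178 genes, called 6% of unchanged lists and 89% of those shifted by 1. The simulated values were independent between genes, which the members of a marker list need not be. Order-statistic intervals over 240 simulated genes covered the true median in 95.9% of runs. The correlation test called 7.5% of unrelated pairs of 13 values and the sign flip test 5%.

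Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.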

Results

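Allele-resolved expression was measured by Smart-seq2 in 42 mouse embryo samples from crosses with PWK/PhJ fathers; the mothers were C57BL/6N in the first 2 tables below. The maternal and paternal alleles were listed separately, as FPKM (fragments per kilobase, scaled to library size). A first table held female 8-cell embryos (3 samples), morulae (3), E3.5 inner cell mass (2), E3.5 trophectoderm (3), E6.5 epiblast (1), E6.5 visceral endoderm (3), E6.5 extraembryonic ectoderm (2) and E9.5 yolk sac (1). A second held control male morulae (4), control female morulae (3) and female morulae with a deletion of the region XRRa on the paternal X chromosome, named Xp XRRa KO in the labels (4). In both tables each group had 1 column per allele that pooled its samples, so spread between samples could not be computed and no group difference in them was tested. The last table held X-linked genes of 13 female E7.5 extraembryonic ectoderm samples named EedmNull, whose mothers carried floxed Eed and Gdf9-Cre, which deletes it in the oocyte. Eed encodes a core subunit of the Polycomb repressive complex PRC2. These 13 embryos had a column per allele each. Read depth was unknown because the tables gave no counts. The cross was made in 1 direction, so strain and parent of origin cannot be separated.

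The stage table addressed when and where the paternal X is silenced. The median paternal share of X-linked expression was 42.6% in 8-cell embryos (95% interval over 259 genes, 38.6 to 45), 26.1% in morulae (22.7 to 30.1), 8.33% in the inner cell mass and 4.42% in the trophectoderm. At E6.5 it was 0.606% in visceral endoderm and 4.78% in extraembryonic ectoderm, against 47.8% in the single epiblast sample (46.2 to 49.4). Autosomal medians stayed between 46.8% (8-cell) and 50% (yolk sac). Over the 220 X-linked genes measured in both columns, the share was lower in morula than in 8-cell by a median of -9.59 points, with 171 genes lower and 44 higher. Trophectoderm was lower than the inner cell mass by -1.40 points over 237 genes, and the epiblast was 35.1 points above the inner cell mass over 219. Among 10000 random expression-matched autosomal lists, none had a median as low as that of the X-linked genes in morula, inner cell mass, trophectoderm, visceral endoderm or extraembryonic ectoderm. The fraction of X-linked genes at a paternal share of 20% or less was 17.4% in 8-cell embryos, 39.0% in morulae, 69.4% in inner cell mass, 82.1% in trophectoderm, 97.2% in visceral endoderm and 87.6% in extraembryonic ectoderm. The epiblast had 4.92% of such genes. Yolk sac, with 145 measured X-linked genes in 1 sparse sample, had a median of 0%.

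Genes differed in how far they followed that median. In 8-cell embryos Rlim, which encodes a ubiquitin ligase that activates Xist, already had a paternal share of 6.81%, and Trap1a, Gnl3l and Psmd10 had 0.358%, 3.33% and 5.80%. Rlim stood at 0.569% in morulae, beside Vbp1, Cetn2 and Prickle3 at 0%. A share of 0% is not read as silencing by itself, because the autosomal gene Pou5f1 also had no paternal FPKM in morulae (maternal 229 FPKM). At the other end, Bex1 had 96.8% in 8-cell embryos and 99.8% in morulae, and Bex4 100% in 8-cell embryos. Genes known to escape X inactivation had higher medians than the chromosome: 43.6% in morulae, 31.9% in inner cell mass, 13% in trophectoderm, 14.6% in visceral endoderm and 20.7% in extraembryonic ectoderm (8 or 9 genes each). In trophectoderm, Kdm6a, a histone H3K27 demethylase, had 34.4%, and Taf1, a subunit of the general transcription factor TFIID, had 36.1%. In extraembryonic ectoderm the highest included Eif2s3x (40.6%), the glycosyltransferase gene Ogt (41.0%), the ribosomal gene Rps4x (44.8%), Slc25a5 (50.3%) and Taf1 (50.9%). In visceral endoderm Eif2s3x had 35.4%, Slc35a2 35.8% and the deacetylase gene Hdac6 23.1%. X-linked housekeeping genes had medians of 41.7% in 8-cell embryos, 24.2% in morulae, 16.8% in inner cell mass, 9.08% in trophectoderm, 1.45% in visceral endoderm and 5.44% in extraembryonic ectoderm. Pgk1, a glycolytic enzyme gene of that list, was at 0% in the inner cell mass. The list of reproductive homeobox and placental genes also held Xlr genes. Its median was 0% in inner cell mass, trophectoderm, visceral endoderm and extraembryonic ectoderm. Plac1 itself was at 0% in all 4, and Rhox4e was at 0% in extraembryonic ectoderm. No homeobox gene of the list reached 1 FPKM in inner cell mass or trophectoderm, so those medians came from Plac1 and Xlr genes. Xlr3a also had 0% in the epiblast sample (1.88 FPKM), so its 0% elsewhere is not read as silencing by itself. Computed as a ratio of summed FPKM, the shares were 22.9% in inner cell mass, 16.4% in trophectoderm, 3.99% in visceral endoderm and 13.9% in extraembryonic ectoderm. With genes of at least 0.1 FPKM the inner cell mass median was 4.39% and the trophectoderm median 2.02%; with at least 5 FPKM the inner cell mass median was 13.9%.

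**Figure D1:**
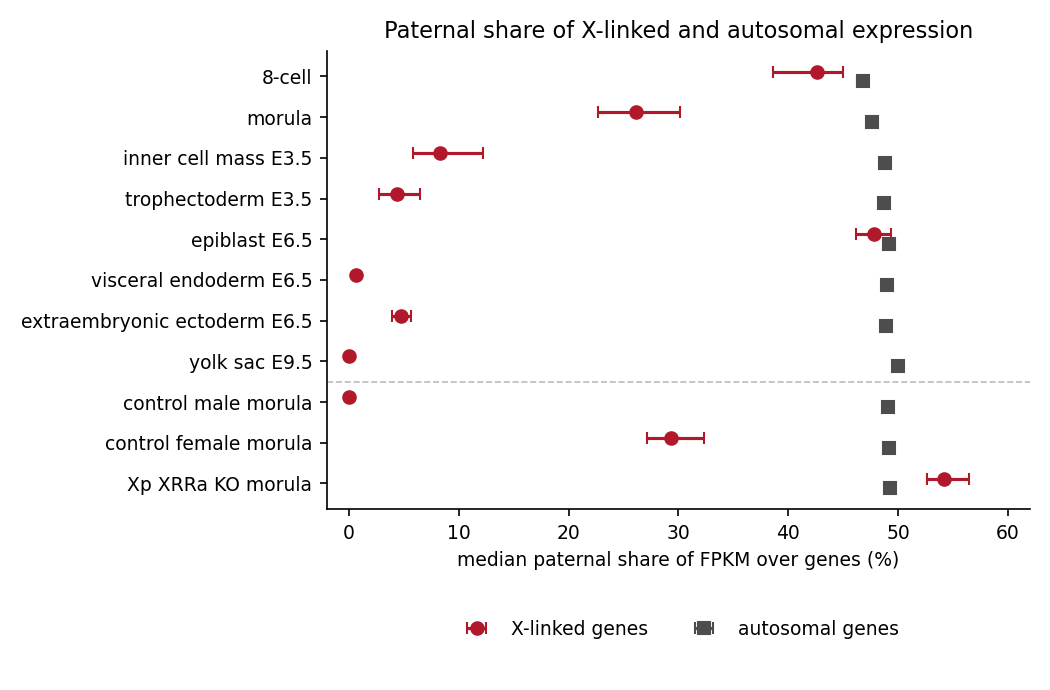
Median paternal share of FPKM (%) over X-linked genes (circles) and autosomal genes (squares) in each group, with 95% order-statistic intervals over genes and the 2 separately normalized tables divided by a dashed line. X-linked medians were 42.6% in 8-cell embryos, 0.606% in visceral endoderm and 0% in yolk sac and control males, while epiblast and Xp XRRa KO morulae stood at 47.8% and 54.2%.

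Xist, the RNA that coats the inactive X, came mostly from the paternal allele in every group of the stage table except the epiblast. Its paternal FPKM was 8.13 in 8-cell embryos, 20.5 in morulae, 10.3 in inner cell mass, 14.5 in trophectoderm, 25.5 in visceral endoderm and 8.06 in extraembryonic ectoderm. The maternal FPKM in those groups was 0.0106, 0.111, 0.699, 0.672, 1.78 and 0.913. In epiblast the maternal allele had 12.7 FPKM and the paternal 5.98. Tsix, which is transcribed antisense to Xist, was mostly maternal in trophectoderm (21.3 against 6.65 FPKM), visceral endoderm (31.9 against 4.70) and extraembryonic ectoderm (22.9 against 1.81). In the morula column it was wholly paternal (38.9 FPKM, with the maternal allele listed at 0). Smart-seq2 libraries do not keep the strand, so reads of Xist and Tsix in their overlap cannot be told apart.

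**Figure D2:**
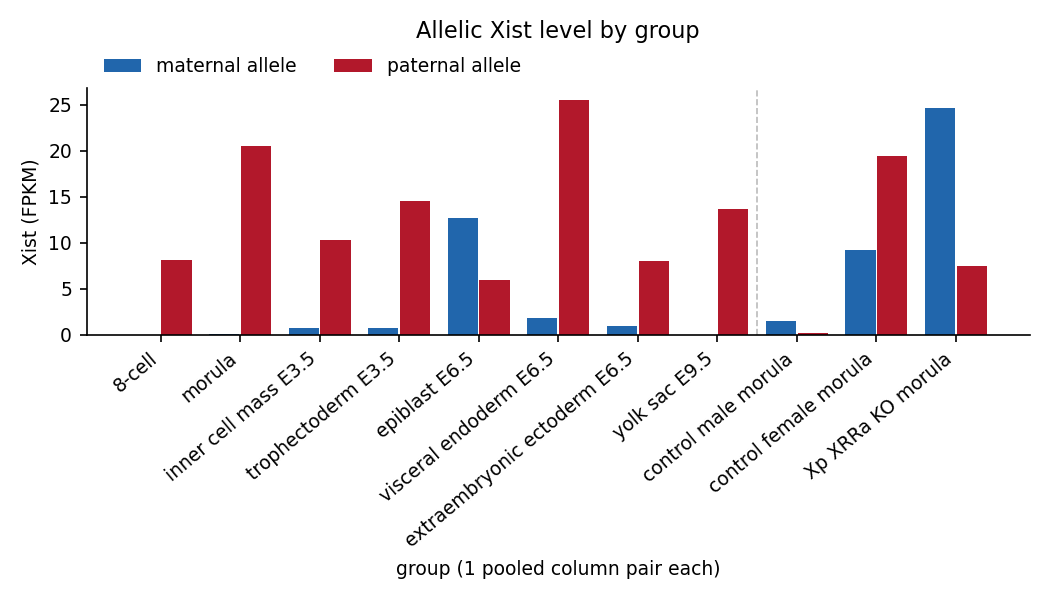
Xist level (FPKM) from the maternal and paternal alleles in each group, 1 pooled column pair per group, with the 2 separately normalized tables divided by a dashed line. The paternal bar was the higher in every stage-table group except the epiblast, and the maternal bar (24.7) was the higher in Xp XRRa KO morulae.

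Imprinted genes served as allelic controls. Paternally expressed imprinted genes had a median paternal share of 96.9% in visceral endoderm (14 genes) and 92.6% in extraembryonic ectoderm (15 genes). Maternally expressed ones had 3.18% and 2.72% (15 and 17 genes). Genes imprinted through maternal H3K27me3, a list that includes Xist, had 93.5% and 96.5% (5 genes each). The 93.5% was the value of Xist itself. In visceral endoderm Gab1 had 72.5% and Smoc1 35.1%, while Sfmbt2 had 97.2% and Slc38a4 100%. In morulae the same 3 lists had medians of 67.5%, 40.6% and 99.5%, from 5, 5 and 3 genes, the last again the value of Xist. PRC2 genes had 40.5% there and 48.8% in extraembryonic ectoderm (7 genes each). Cohesin and CTCF genes had 45.9% and 47.7% (11 genes each). Y-linked genes of the fixed list were at 0 for both alleles in every group, male morulae included, so they gave no check of sex. Primitive blood and endothelium markers had 4 members or fewer at 1 FPKM in each stage-table group.

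Markers of each lineage were compared next, with log2 ratios on FPKM plus 1 here and below. From 8-cell embryo to morula, the 5541 genes with at least 5 FPKM in 1 of the columns had a median log2 ratio of 0.49. Of these, 1766 were at least 2-fold higher and 344 lower. FPKM is scaled to library size, so this offset is not read as more RNA per embryo. The split carries the same offset. The pluripotency factor gene Nanog stood at 2.95 FPKM in 8-cell embryos and 121 in morulae (log2 ratio 4.95), and Pou5f1 at 23.3 and 229. Among trophectoderm markers, 9 of 11 were at least 2-fold higher in morulae (list median 1.65, 99.9th percentile of random lists), including the keratin genes Krt8 (3.21) and Krt18 (2.24) and the transcription factor gene Cdx2 (2.88). Other high ratios were in Ass1 (4.70), Nppb (3.88), Tinagl1 (3.85) and St14 (3.65), and low ratios included Rpph1 (-4.96), Omt2b (-3.20), Spic (-2.76) and Mixl1 (-2.76). X-linked genes had a median of -0.06, below the range of 0.37 to 0.64 of random lists.

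The inner cell mass exceeded trophectoderm in 11 of 13 pluripotency genes by at least 2-fold (list median 2.48), above all 10000 random lists. Tdgf1, a co-receptor for Nodal, had 241 against 0.946 FPKM (6.96), Utf1 had 171 against 13.1 (3.61) and Gdf3 66.7 against 8.34 (2.86), while Fgf4 had 25 FPKM and was listed at 0 in trophectoderm. Of 11 primitive endoderm markers, 7 were at least 2-fold higher and 2 lower (median 1.61, above all random lists), with Sox17 at 3.80 and Pdgfra at 2.88 but Apoa1 at -3.07 and Dab2 at -1.60. In trophectoderm, 12 of 15 trophectoderm markers were at least 2-fold higher (median -1.70), among them Tspan8 (-3.88), the T-box factor gene Eomes (-3.46), Gata2 (-3.13) and Id2 (-3.09), and Hand1 was lower (2.57). Over all genes above 0 in both, high ratios included Upp1 (6.26), Spic (5.78), Ephx2 (5.75) and Etv5 (5.60) in the inner cell mass, and low ones BC051665 (-8.32), Slc39a2 (-5.34), Il6 (-4.63), Tmem54 (-4.42) and the X-linked placental gene Plac1 (-4.16) in trophectoderm. The PRC2 genes Eed (1.35) and Ezh2 (1.27) were higher in the inner cell mass.

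At E6.5 each tissue was set against the mean of the other two. Visceral endoderm was at least 2-fold higher in all 18 measured endoderm markers (median 3.92), including the apolipoprotein gene Apoa1 (1324 against 55.2 FPKM), Ttr (693 against 33.0), Afp (467 against 20.5) and the scavenger receptor gene Cubn (77.4 against 2.47). Extraembryonic ectoderm was higher in 12 of 16 of its markers (median 2.83), with Elf5 at 124 against 0.130 FPKM, Bmp4 at 64.0 against 0.336, Wnt7b at 49.1 against 0.0373 and Hand1 at 45.5 against 0.0233. The transcription factor gene Tfap2c (5.98) was also among the highest there. The epiblast sample had Slc7a3 at 209 against 1.80 FPKM, Pou5f1 at 79.4 against 7.19, Tdgf1 at 104 against 10.7 and Fgf4 at 19.8 against 0.154. Low in epiblast were Spink3 (-10.17), Apoa1 (-8.07), Ttr (-7.94) and Afp (-7.44). The list of postimplantation epiblast genes had a median of -0.75 in epiblast over the other tissues, with Mixl1 listed at 0 there, and 0.91 in visceral endoderm; with genes of at least 5 FPKM on average, the epiblast median was 0.23. Of the maternal decidua markers, the growth factor gene Bmp2 was the highest in these tissues, with 16.0 FPKM in visceral endoderm. The median of all genes was shifted by -0.10 in epiblast, -0.38 in visceral endoderm and 0.36 in extraembryonic ectoderm. Some abundant genes such as Ppia were listed at 0 in single columns, and no ratio is given for those.

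The Xp XRRa KO morulae addressed what the region does for silencing of the paternal X. The median paternal share of X-linked expression was 54.2% (52.6 to 56.5, 280 genes) in the deleted morulae and 29.3% (27.1 to 32.4, 259 genes) in control female morulae. Over the 242 genes measured in both, the share was higher by a median of 20.8 points (18.5 to 25), with 214 genes higher and 27 lower. The autosomal difference was 0.159 points over 7546 genes. Set against the morulae of the stage table, a reference chosen only after the result was seen, the share was 24.6 points higher over 234 genes. Of 73 genes with a share of 20% or less in control females (median 10.9%), 48 lay between 30% and 70% in the deleted morulae and 7 stayed at 20% or less. Rlim stood at 4.17% and 48.2%, the cohesin gene Smc1a at 12.1% and 66.0%, Fam122b at 9.58% and 62.4%, the lysosomal enzyme gene Gla at 14.9% and 54.2%, and Hnrnph2 at 10% and 57.7%. Among genes at 5 FPKM in both columns, the largest differences were in Tceal8 (21.8% and 100%), Ngfrap1 (21.8% and 97.7%), Wbp5 (18.1% and 94.0%), the sterol enzyme gene Nsdhl (6.42% and 81.7%), Bex4 (19% and 90.1%) and Morf4l2 (19% and 81.1%). In the stage-table morulae Bex4 had 96.2%, Ngfrap1 82.8% and Wbp5 71.7%, at 2.47 to 3 FPKM, so for these 3 genes the control female column was the one apart. Housekeeping genes had list medians of 27.1% in control females and 53.1% in deleted morulae, and known escape genes 36.2% and 51.2%. Ogt (50% and 55%), Eif2s3x (47.7% and 55.1%) and the ribosomal gene Rpl10 (51.4% and 54.0%) had balanced shares in both. The share was lower in the deleted morulae for Xist (68.0% and 23.2%), Slc10a3-ubl4 (59.2% and 15.8%), the PRC2 histone-binding gene Rbbp7 (80.3% and 41.0%), Tsix (53.3% and 23.3%) and Txlng (52.0% and 30.4%). Rbbp7 had 23.5% in the stage-table morulae, so its direction depended on the reference. In control male morulae, which carry only a maternal X, the median was 0%, and 136 of 139 X-linked genes at 5 FPKM had a paternal share of 5% or less. The exceptions included Gm5643 (75%) and E530001F21Rik (83.5%), whose shares are therefore not read as paternal expression.

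**Figure D3:**
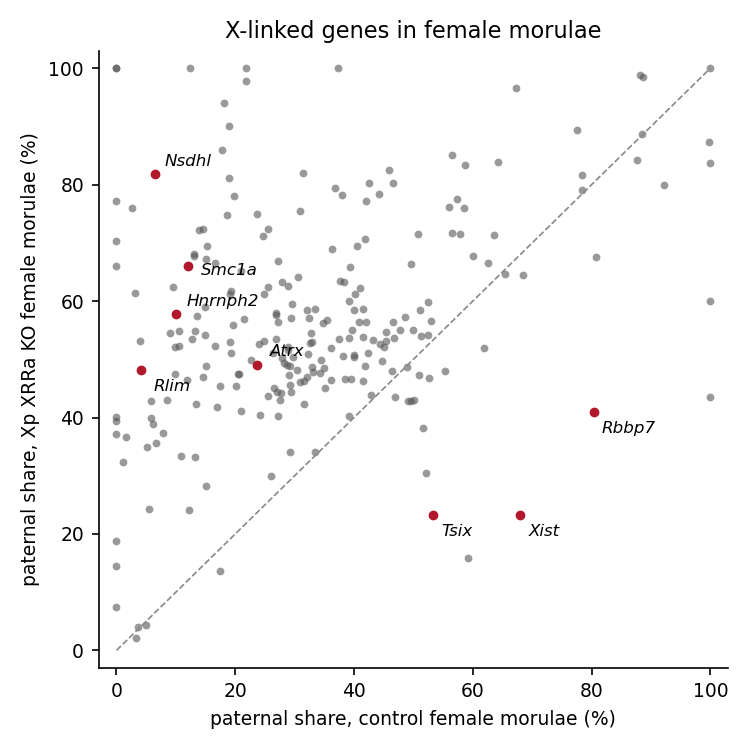
Paternal share (%) of 242 X-linked genes in control female morulae (horizontal) and Xp XRRa KO female morulae (vertical), 1 point per gene, with equality dashed and 8 genes named. 214 genes lay above the line and Xist, Tsix and Rbbp7 were among the 27 below it.

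Xist level was close in sum and shifted between alleles. Its total was 32.1 FPKM in deleted and 28.6 FPKM in control female morulae (log2 ratio 0.16). The maternal allele had 24.7 against 9.15 FPKM (1.34) and the paternal allele 7.44 against 19.5 (-1.28). Tsix had 18.1 against 17.1 FPKM from the maternal allele and 5.49 against 19.5 from the paternal (-1.66). The libraries do not keep the strand, so Xist and Tsix are not read as independent results. In the morulae of the stage table, normalized separately, maternal Xist was 0.111 FPKM. The control female share of X-linked genes differed from that of those morulae by 1.43 points over 221 genes.

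Paternal transcripts of X-linked genes were higher in the deleted morulae by a median of 1.90-fold over 141 genes, against 1.01-fold for 3894 autosomal genes. By size, 66 X-linked genes were at least 2-fold higher and 4 lower. Among genes above 0 in both, the largest were Hnrnph2 (1.99 to 25.4 FPKM, log2 ratio 3.14), Smc1a (0.825 to 13.5, 2.99), Nsdhl (2.61), the splicing regulator gene Nono (2.51), Ngfrap1 (2.41), Nxt2 (2.40), Pbdc1 (2.33), Hsd17b10 (2.29), the kinesin gene Kif4 (2.25) and Acsl4 (2.24). In the X inactivation center, Rlim (2.17) was higher from the paternal allele, beside the lower Xist and Tsix. Maternal transcripts of X-linked genes were 0.811-fold of the control level over 134 genes, with 23 at least 2-fold lower and 7 higher. For 3929 autosomal genes the maternal level was 0.989-fold, with 211 lower and 183 higher. The lowest maternal alleles were Ngfrap1 (23.7 to 0.910 FPKM, -3.69), Wbp5 (-3.67) and Bex4 (-2.88). These are the genes named above whose share in control females stood apart, so no loss of maternal expression with the deletion is read from them. The X-linked median of 0.811-fold is over all 134 genes. Higher paternal and lower maternal levels thus both enter the higher paternal share. That share, 54.2% in deleted morulae, lay above the 47.8% to 50.9% of random autosomal lists.

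In total expression, X-linked genes were 1.26-fold higher in the deleted morulae (28 of 186 at least 2-fold higher, 2 lower), against 1.03-fold for autosomal genes. Housekeeping genes on the X had a list median of 0.45 on the log2 scale (99.99th percentile of random lists), with the chromatin remodeler gene Atrx (4.79 to 15.4 FPKM, 1.51), Kif4 (1.49), Smc1a (1.45), Las1l (1.27) and Fmr1 (1.04) the most different. Known escape genes had 0.57 (Kdm6a 1.02, Eif2s3x 0.63) and cohesin genes 0.55 (Stag2 0.88, Nipbl 0.80). Against control males the cohesin median was 0.02. Over all genes, 239 of 5590 were at least 2-fold higher and 197 lower. Among those above 0 in both, the highest ratios were in the X-linked glycerol kinase gene Gyk (2.74), Slc24a5 (2.36), the DNA repair gene Brca2 (1.73 to 10.7 FPKM), Acsl4 (2.07), Kdm4c (1.99), Klf17 (1.88), A830080D01Rik (1.87), Id3 (1.86), Enpp3 (1.85) and Arg1 (1.84). The lowest were Spp1, which encodes osteopontin (30.9 to 2.41 FPKM, -3.23), S100a6 (122 to 14.3 FPKM), Rbp2 (-2.50), Rpl29 (-2.43), the Wnt inhibitor gene Dkk1 (6.43 to 0.617 FPKM), Mvk (-2.09), Snhg9 (-2.01), Tmem160 (-1.93), Fbp1 (-1.92) and Zap70 (-1.91). Pluripotency genes had a median of 0.35 (98.3th percentile), with Tbx3 at 1.37 and Tdgf1 at 1.03, and PRC2 genes one of 0.30. Extraembryonic ectoderm markers had -0.54 (0.40th percentile) with none past 2-fold, trophectoderm markers -0.06 with Krt18 at -1.39, and primitive endoderm markers -0.07. The X-linked reproductive homeobox and placental genes had 0.10 and the endothelial markers 0.47. Genes imprinted through H3K27me3 had 0.34, led by Jade1 (1.63), paternally expressed imprinted genes 0.55 and maternally expressed ones -0.14. Oocyte genes were lower (median -1.04, 0.01th percentile): the growth factor gene Gdf9 had 0.180 against 3.51 FPKM and Ooep 8.12 against 19.5, while the oocyte linker histone gene H1foo was 3.24 in control females and listed at 0 in deleted morulae. Control males stood near the deleted morulae for Gdf9 (0.189 FPKM) and H1foo (listed at 0), so for these genes the control female column was the one apart. Males were also nearer to the deleted morulae than to control females for 7 of the 10 lowest genes named above (all but Rbp2, Rpl29 and Mvk), such as Spp1 (5.94 FPKM) and S100a6 (36.3). This held for 1 of the 10 highest, Slc24a5 (52.6 FPKM), and over all genes past 2-fold for 68 of 239 higher and 49 of 197 lower. In control females, 4 of 7 measured oocyte genes had a paternal share of 20% or less. With columns scaled to equal medians 205 genes were higher and 222 lower, which turns the balance. Without a filter on low values 436 genes were higher and 318 lower, and 378 were higher with a mean FPKM of at least 1.

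Control female morulae were set against control male morulae, which have a single X, though the pools can differ in more than sex. X-linked genes were 1.33-fold higher in females (25 of 168 at least 2-fold higher, 7 lower) while autosomal genes stood at 0.933-fold. Deleted females had 1.60-fold of the male level. From the maternal allele alone, X-linked expression was 0.855-fold of the male level in control females and 0.722-fold in deleted females, against autosomal values of 0.954-fold and 0.935-fold. Xist had 28.6 against 1.58 FPKM (3.52) and Tsix 36.6 against 2.40 (3.47). Without the strand, these are not independent results. Among genes above 0 in both, the others with the highest ratios were Dusp1, a MAP kinase phosphatase gene (3.05), Fcgr3 (2.73), Bex1 (2.71), Gm6880 (2.47), Gm13128 (2.47), Zscan5b (2.39), the natriuretic peptide gene Nppb (18.1 against 3.13 FPKM) and Spp1 (30.9 against 5.94 FPKM). The lowest were Slc24a5 (-3.35), Gstm1 (-2.30), the kinetochore gene Nuf2 (-2.09), Cdkn3 (-1.92), Pgk1 (-1.90), Tspan8 (-1.88), 3110009E18Rik (-1.81), Nme7 (-1.79), Gpx7 (-1.77) and 4930550L24Rik (-1.77). X-linked housekeeping genes had a list median of 0.26 (Stag2 1.66, Pdha1 1.23, Smc1a -0.97) and escape genes one of 0.55 (Pbdc1 1.10, Eif2s3x 0.70), both above 99.9% of random lists. Trophectoderm markers were lower in the female column (median -0.70, below all random lists), with Tspan8 (-1.88), Krt8 (-1.40) and Dppa1 (-1.15) but Hand1 at 1.14. Oocyte genes were higher (0.99, with Gdf9 at 1.92 and Zp3 at 0.99). Random-list percentiles hold no spread between embryos, so a difference between these 2 pools is not read as one between the sexes. Cohesin genes had -0.44 and pluripotency genes 0.15. Deleted females were nearer to males for Spp1 (2.41 FPKM), Gdf9 (0.180) and Slc24a5 (26.1), where control females were the ones apart. For Zp3 (11.8 FPKM), Tspan8 (11.4) and Krt8 (137), deleted females were nearer to control females. Over all genes 152 of 5562 were at least 2-fold higher and 167 lower. With columns scaled to equal medians these were 179 and 116, with no filter on low values 296 and 358, 243 and 290 with a mean FPKM of at least 1, and 113 and 107 with a mean of at least 5.

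In EedmNull extraembryonic ectoderm, the question was whether the paternal X stays silenced when the oocyte lacks Eed. The median paternal share per embryo averaged 33.9% ± 26.1 (SD, n = 13) and ran from 0% to 80.5%. Against 50% the two-sided sign-flip permutation test gave p = 0.0482, with 9 of 13 embryos below 50%. As a ratio of summed FPKM the mean was 37.7% ± 21.2 (p = 0.0584). Embryos 1 and 4 had 0.198% and 0%, embryos 3 and 5 had 6.22% and 7%, embryo 2 had 20.5% and embryo 6 had 25.8%. The next were embryo 10 (37.2%), embryo 7 (44.4%), embryo 9 (48.1%), embryo 12 (53.0%), embryo 8 (55.6%), embryo 11 (62.2%) and embryo 13 (80.5%). The wild-type E6.5 extraembryonic ectoderm, a day earlier and from another table, had 4.78%. No control tissue of the same day was among the samples.

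Xist in these embryos totalled 0.955 ± 0.419 FPKM (SD, n = 13), and its paternal share averaged 58.8% ± 30.1. Total Xist was below 1 FPKM in 9 of the 13 embryos, so most of these Xist shares lie under the minimum used for other genes and rest on low levels. The X-linked share was lower in embryos with a higher paternal share of Xist: Pearson's r was -0.912 (permutation p = 3e-05, adjusted 0.00012) and Spearman's rho -0.896 (p = 6e-05, adjusted 0.00024) over 13 embryos in a family of 4 relations. Without the 2 embryos farthest from the median Xist share (8 and 13) r was -0.896 (p = 0.00051). The 4 embryos with a paternal Xist share above 80% had X-linked shares up to 7%, and the 9 others started at 20.5%; within these 9 r was -0.740 (exact permutation p = 0.0221) and rho -0.733 (p = 0.0311). The 3 other relations of the X-linked share did not pass. These were with total X-linked FPKM (r 0.391, p = 0.188, adjusted 0.188; rho 0.516, p = 0.0754, adjusted 0.1), with genes above 0 (r 0.553, p = 0.0515, adjusted 0.103; rho 0.549, p = 0.0541, adjusted 0.1) and with total Xist (r -0.423, p = 0.151, adjusted 0.188; rho -0.368, p = 0.217, adjusted 0.217). Without embryos 6 and 12 the relation with total X-linked FPKM had r 0.753 (p = 0.00813), without embryos 3 and 4 that with genes above 0 had 0.291, and without embryos 1 and 2 that with total Xist had -0.174.

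**Figure D4:**
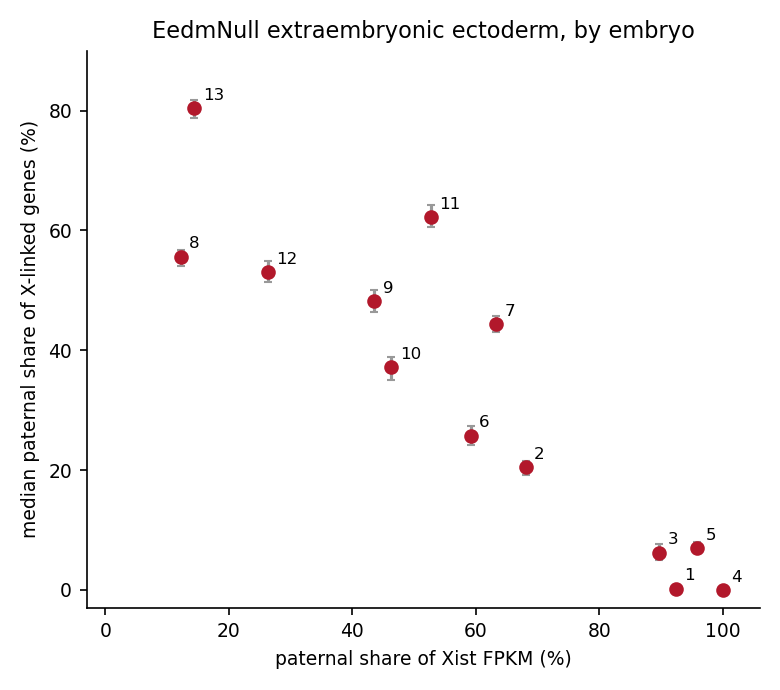
Median paternal share of X-linked genes (%, vertical, with 95% order-statistic intervals over genes) against the paternal share of Xist FPKM (%, horizontal) in 13 EedmNull embryos, numbered as in the table. Embryos 1 and 4 combined paternal Xist with X-linked shares of 0.198% and 0%, and embryo 13 had the highest X-linked share, 80.5%.

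Gene by gene, 28 of 300 X-linked genes had a paternal to maternal ratio different from 1 over the 13 embryos (limma, Benjamini-Hochberg adjusted p under 0.05): 27 were skewed to the maternal allele and 1, Gm5643, to the paternal. Centred on the embryo median, a fit chosen only after the result was seen, 37 lay to the maternal side and 34 to the paternal. Centring balances the sides by construction, so this split does not measure skew of the chromosome. Nono had the lowest log2 ratio, -3.94 ± 0.52 (SE; limma adjusted p = 0.000188, maternal higher in 13 of 13 embryos), followed by Pbdc1 (-2.62), the purine salvage gene Hprt (-2.40), Rnf128 (-2.33), Lage3 (-2.29), the homeobox gene Rhox4e (-2.20), Apoo (-2.18), Ldoc1 (-2.05), Fhl1 (-2.04) and Cited1 (-1.92); in each of these the maternal allele was the higher in at least 9 of 13 embryos. Nono also had a paternal share of 14.2% in the epiblast sample, and Gm5643 one of 75% in male morulae. Among fixed lists, 4 of 34 housekeeping genes were skewed to the maternal allele (5 adjusted over the list alone), 2 of 8 known escape genes (2 adjusted over the list alone) and 2 of 10 reproductive homeobox and placental genes (2 adjusted over the list alone). At an unadjusted p under 0.05, 151 were maternal and 2 paternal. The count moved with single embryos: 4 were maternal without embryo 10, 5 without embryo 2 or 6, 6 without embryo 1, 3 or 5, 7 without embryo 4, 12 without embryo 7, 42 without embryo 11 and 189 without embryo 13.

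Some genes followed the share of their embryo less than 1 to 1, in a fit chosen only after the embryo values were seen. The slope of each gene's share on the embryo median was below 1 for 35 of 224 genes and above 1 for 6 (limma, adjusted p under 0.05); slopes average close to 1 by construction. Taf1 had the flattest slope, 0.0838 ± 0.0727 (SE; limma adjusted p = 2.6e-07, n = 13), with shares between 41.4% and 64.2% in every embryo. Ogt had 0.164 (36.6% to 53.2%), Atrx 0.322, the RNA-binding protein gene Rbm3 0.344, Rps4x 0.370, Eif2s3x 0.391 (34.5% to 67.2%), Kdm6a 0.451, the methyltransferase gene Suv39h1 0.471, Ercc6l 0.554, the demethylase gene Kdm5c 0.574 and the RNA helicase gene Ddx3x 0.657. Of 8 known escape genes 7 were below 1 (8 adjusted over the list alone), as were 7 of 28 housekeeping genes (7 adjusted over the list alone). On the list of reproductive homeobox and placental genes 1 of 7 was below 1, Xlr4b, which is neither (1 adjusted over the list alone). Low slopes also came from genes that stayed mostly maternal in every embryo, Nono (0.375, 0.0742% to 33.8%) and Pbdc1 (0.367, 2.30% to 30.5%), and from Gm5643 (0.133), not read as paternal expression. In male morulae Taf1, Ogt, Atrx and Rps4x had paternal shares of 0.975%, 0.524%, 0% and 0.751%. The 35 genes had a median share of 19.5% in wild-type E6.5 extraembryonic ectoderm, and the 188 other genes measured there one of 4.72%. Without single embryos the count below 1 ran from 23 to 38 and that above 1 from 1 to 6.

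**Figure D5:**
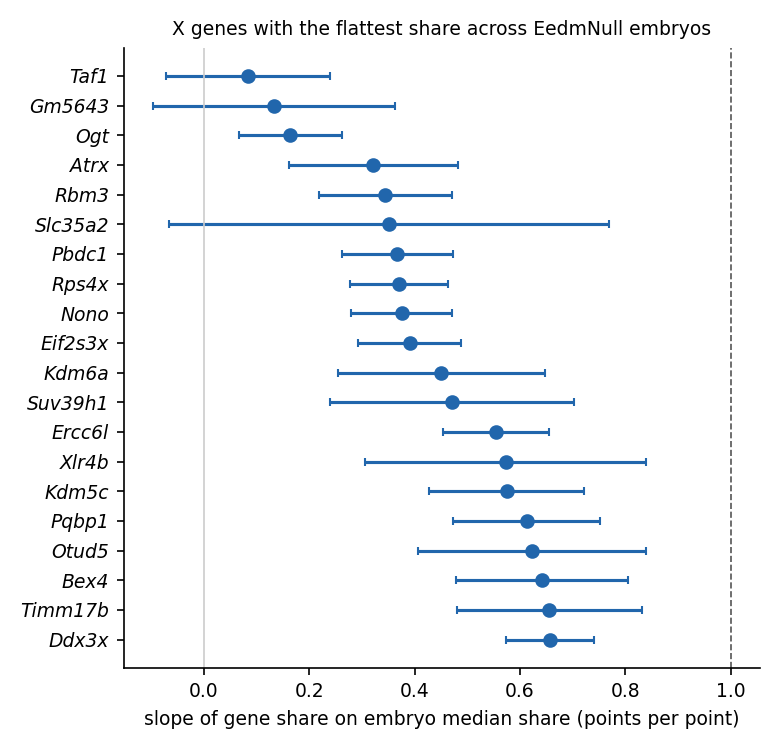
Slope of a gene's paternal share on the embryo median share (points per point, with 95% intervals) over 13 EedmNull embryos for the 20 flattest of the genes that passed. Taf1 lay at 0.0838 and Ogt at 0.164, against 1 (dashed) for a gene that follows its embryo.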

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

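Most choices were fixed before the data were examined, and choices were replaced in turn, giving 192 alternatives for 38 results. Of these, 138 left the result the same, 43 moved it, 10 weakened it and 1 reversed it. Counts of genes were judged by size in each direction alone, so a turned balance between directions could still count as the same. Chosen only after the results were seen were fits centred on the embryo median, the stage-table morula as reference, the difference of the medians, leaving out genes listed at 0, and median scaling of control females over males. So were all alternatives for the relation with Xist and leaving out single embryos for the mean share. No paired analysis was possible because the pooled columns hold all replicates of a group and the EedmNull embryos have no partner samples; single samples could be left out only among those embryos.

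As a ratio of summed FPKM, which gives abundant genes more weight, the paternal X share was 35.5% in morula, 22.9% in inner cell mass, 16.4% in trophectoderm, 45.6% in epiblast, 3.99% in visceral endoderm, 13.9% in extraembryonic ectoderm, 4.11% in yolk sac, 0.564% in control males, 37.2% in control females and 52.5% in Xp XRRa KO morulae. The difference between Xp XRRa KO and control female morulae was then 15.3 points, and the EedmNull mean was 37.7%. With a minimum of 0.1 FPKM the share was 22.6% in morula, 4.39% in inner cell mass, 2.02% in trophectoderm and 0.391% in visceral endoderm. With a minimum of 5 FPKM it was 13.9% in inner cell mass and 32.5% in control females, and the difference between Xp XRRa KO and control females was 17.6 points. With the stage-table morula as reference it was 24.6 points. Relative to the autosomal median it was 45.8% in 8-cell embryos, 1.63% in visceral endoderm, 5.83% in extraembryonic ectoderm and 0.932% in control males. The cause of the shifts was not tested.

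The number of genes past 2-fold between Xp XRRa KO and control females was 436 higher and 318 lower without a filter, and 378 higher at a mean of at least 1 FPKM. Between control females and males it was 296 and 358 without a filter, 243 and 290 at a mean of at least 1 FPKM, and 113 and 107 at a mean of at least 5, where the balance turned. With columns scaled to equal medians the balance turned in both comparisons, to 205 higher and 222 lower for Xp XRRa KO and to 179 and 116 for control females over males. More genes were examined under the looser filters, which by construction adds genes.

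In EedmNull embryos, genes skewed to the maternal allele numbered 11 without a filter, 17 at a mean of at least 5 FPKM, and from 4 to 189 when single embryos were left out. Centred on the embryo median, which balances the sides by construction, 37 were skewed to the maternal and 34 to the paternal side. The mean share ran from 30.02% to 36.7% without single embryos. Over its 17 alternatives p ran from 0.0158 to 0.0976 (sign-flip permutation, n = 13), so the difference from 50% was not firm. The relation with Xist kept an r from -0.946 to -0.892 without single embryos and had -0.868 as a ratio of sums. The cause was not tested.

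The median of postimplantation epiblast genes in epiblast over the other tissues turned from -0.75 to 0.23 at a mean of at least 5 FPKM; the cause was not tested. The other lineage alternatives (26 of 27) and all 12 for imprinted genes left the result the same.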

Other observations

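The tests in this part were chosen only after the results were seen, although the relation with Xist and the shares of X-linked, autosomal and imprinted genes were planned measurements. Genes whose share followed that of the EedmNull embryo less than 1 to 1 were neighbours, in the order of tested X-linked genes, more often than in random draws. Of 213 tested genes in chromosome order, 35 were called with a slope below 1 (limma, adjusted p under 0.05), from 0.0838 (Taf1) to 0.853 (C330007P06Rik). They formed 16 neighbouring pairs against a median of 6 in random draws (1-sided permutation p = 1e-05, the smallest the draws can give). One run held Nono, Taf1, Ogt, Ercc6l, Rps4x and Cited1, and others Otud5, Pim2, Slc35a2, Pqbp1 and Timm17b, or Suv39h1, Rbm3 and Tbc1d25. The cause was not tested.

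A lower paternal share nearer to Xist was examined in morulae. Over 237 genes the share and gene-order distance had a rho of 0.281, but circular shifts of the gene order gave p = 0.350, so the relation stays undecided. Control female (0.133) and Xp XRRa KO morulae (-0.0427) had weaker values.

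The higher paternal X share in Xp XRRa KO morulae was weighed against 3 technical explanations. A shift of the whole library's allele balance would move autosomal genes, which differed by 0.159 points. Exchanged alleles would lower paternally expressed imprinted genes, which had a median paternal share of 96.3%. An earlier stage would give a share no higher than that of 8-cell embryos, but 54.2% lay above the 8-cell interval, which ended at 45%. That interval describes spread over genes and not over embryos, and no stage before 8-cell was sampled, so an earlier stage stays open. Autosomal genes lower in morula than in 8-cell embryos had a median of 0.47 in Xp XRRa KO over control females (36 genes, random lists -0.12 to 0.30), as an earlier stage would give. The 425 genes higher in morula had 0.12 (random lists 0.01 to 0.12), where an earlier stage would lower them.

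Maternal Xist of 9.15 FPKM in control female morulae, against 0.111 in the stage-table morulae, was weighed likewise. Separate normalization cannot change a share, and the paternal share of Xist differed by 31.5 points. Reads of Tsix counted as Xist stay undecided: maternal Xist over Tsix was 0.536, far above inner cell mass (0.0288), trophectoderm (0.0316), visceral endoderm (0.0559) and extraembryonic ectoderm (0.0399), but below the 0.6 of males. Males among the females could not explain it, since the value was 6.37-fold that of males. An unusual embryo in the pool stays open: H1foo (3.24 FPKM), Gdf9 (3.51) and Zp1 (1.05) were wholly maternal in control females, against 0, 0.189 and 0 in males, and the pooled column shows no single embryo.

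The spread among EedmNull embryos had 3 technical explanations tested. Maternal tissue would lower paternal Xist together with the paternal X share, a positive relation, and r was -0.912 (permutation p = 3e-05, n = 13). Sampling noise would make separate genes disagree, and embryo medians over 2 separate sets of genes had r 0.999. Loss of the paternal X in the lowest embryos is excluded by 4 genes with paternal reads there, such as Taf1 (49.1% and 45.7%) and Ogt (39.5% and 36.6%). Incomplete deletion of Eed in the oocyte was not testable with X-linked genes only, and no biological explanation was tested.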
